A study of Homo sapiens with 6 samples.

How the data were processed

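RNA sequencing values of 6 samples of human endometrial stromal cells were analysed, 3 control and 3 GOLPH3 knockdown. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a SMARTer mRNA kit, and cells were grown in a medium with fetal bovine serum. The deposited table gave FPKM values, rounded by the authors to 2 decimals, with a versioned Ensembl gene ID, symbol, chromosome and gene type per gene. The submitters' processing notes name fastp, a read trimmer, and featureCounts, a read counter, without versions; the aligner, genome build and annotation are not given in the sources used here. FPKM values depend on gene length and on the total of each library, so a shift in a few abundant genes moves all others. Whether counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands could not be told apart. The table held 6025 genes, and all 6 columns of values were matched to samples by name.

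Gene IDs, without their version, were matched to GENCODE release 29 on GRCh38, where 5921 were found, 1227 of them with the same version. Coordinates, gene lengths and GC content come from that annotation and not from the authors' files. GC content and length were those of the longest protein-coding transcript of a gene, and were available for 98.2% of the tested protein-coding genes. For lncRNA genes the longest transcript was used (94.7% with a value).

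The fragment total behind each sample's FPKM was recovered from the values. For genes with the same ID version and at most 600 bases of merged exons, the total was sought at which FPKM values up to 60 fragments became whole multiples of the value of 1 fragment. At the total found, 100.0% of the values of 187 to 195 genes per sample were within 0.15 of a whole number. On simulated data the total was recovered within 0.008%. The totals set counting error only. Replicate pairs differed by 1.8 to 3.62 times the counting noise, so no pair was treated as 1 library.

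The main test was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(FPKM + 1), two-sided, over genes with a mean of at least 1 FPKM across the 6 samples, knockdown minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount of 1 makes fold changes smaller for genes at low level; folds given beside FPKM values are ratios of group means without it. A count model was not used, since the values are not counts. The steps were tested on simulated data made from the 2944 tested genes of the knockdown against control comparison. Log2 changes of 0.25, 0.5 and 1 were recovered for 61%, 93.2% and 98.5% of changed genes, and 14 of 2744 unchanged genes were called. Most simulated genes were unchanged, whereas 2940 of the 2944 genes passed in the data. These rates check the steps and do not carry over to the data. Single values were compared by an exact permutation test in SciPy 1.17.1. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.

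The 26 gene lists cover decidualization, Golgi functions, signalling, stress and metabolic pathways, splicing factors and markers of other cell types. Lists with at least 5 tested members were compared with the other tested genes by limma's camera with a preset correlation of 0.01, again with an estimated correlation, on ranks, and with fry. Because 2940 of the 2944 tested genes changed, camera here sets a list almost wholly against other changed genes. For the comparison with lists of like GC content, each protein-coding member was replaced 10000 times by a gene drawn from the 100 genes of nearest GC content, and the number of risers and the median log2 fold change were compared, two-sided, each with Benjamini-Hochberg adjustment over 19 lists. The smallest p the draws can give is 0.0002. Members were drawn independently of each other, so these p-values are too small where the members of a list move together. Lists of ribosome biogenesis genes, metallothioneins and cytosolic aminoacyl-tRNA synthetases were drawn up once some of the values were known and appear only among the additional observations.

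Named genes were chosen by a rule: GOLPH3; the 8 genes with the largest rise and the 8 with the largest fall in limma's log2 fold change of FPKM + 1 among called genes whose groups did not overlap; and the 2 members of each list with the smallest p (3 for the decidualization lists). Features without a gene symbol and pseudogenes were left out, as were genes of the sex chromosome Y and the inactivation transcript of X. Other genes in the text were chosen after their values were seen, as examples or as exceptions to their list.

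The alternatives were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, rescaling to a sum of 1000000, median-of-ratios factors, TMM factors, quantile normalization, limma without the trend, with robust estimates or with sample weights, the replicate number as a block, and leaving out each sample in turn. An added alternative multiplied the knockdown values by the offset between the smallest rise and the smallest fall. Rescaling to a common sum, median-of-ratios factors and the added offset shifted the log2 fold changes of single genes by a median of −0.58, −0.42 and 0.24; TMM factors and quantile normalization shifted them by a median of less than 0.1. Folds in the text are on the scale of the FPKM values as deposited.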

Results

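Gene expression was measured by RNA sequencing in cells labelled human endometrial stromal cells, the fibroblast-like cells of the uterine lining that differentiate into decidual cells before implantation. All 6 samples carried the label decidualization, the name of that differentiation. In 3 samples GOLPH3 had been knocked down by transfection of a plasmid, and the 3 control samples had received the empty vector. GOLPH3 is a peripheral membrane protein of the trans-Golgi that binds phosphatidylinositol 4-phosphate. The comparison asked how lowering it altered gene expression, and in particular transcription factors tied to decidualization; alternative splicing was not analysed here. The table used here held FPKM values, fragment counts normalized to gene length and library total, for 6025 genes, of which 4771 were protein-coding and 978 were lncRNA genes. The fragment totals behind the FPKM values, recovered from the step between low values, were 27800000, 40000000 and 37400000 in control samples 1 to 3 and 32200000, 38600000 and 34600000 in knockdown samples 1 to 3. The FPKM values of the table summed to 67212 to 67740 in the control samples and to 102308 to 103085 in the knockdown samples.

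Small differences were missing from the table. Among the 1416 genes above 2 FPKM in every sample, the smallest rise in mean FPKM was 0.70 and the smallest fall was −1.30 on the log2 scale, with no gene between. Counts of changed genes therefore describe this table and not the transcriptome, and a listed gene outside the table was not analysed here. The 3 knockdown values lay above all 3 control values for 3228 genes and below them for 2690 genes, and the groups overlapped for 107 genes. Replicates lay close together. Among 867 genes above 5 FPKM in all samples, the median coefficient of variation was 3.17% in the control and 2.07% in the knockdown samples. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

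GOLPH3 itself (ENSG00000113384.14; GRCh38 chromosome 5, 32124704 to 32174350, minus strand, protein-coding) was lower in every knockdown sample. Its FPKM was 18.65, 21.15 and 20.08 in control samples 1 to 3 and 3.05, 2.88 and 3.07 in knockdown samples 1 to 3. The mean fell from 19.96 ± 1.25 to 3.0 ± 0.10 FPKM (SD, n = 3 in each group, as for all later values), so that 15% of the control level was left, a 6.65-fold difference. On the log2(FPKM + 1) scale the change was −2.39 with a standard error of 0.05 and a Benjamini-Hochberg adjusted p of 1.575e-09 in limma. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest value that 3 against 3 samples allow.

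Genes of the cellular response to low oxygen were among the steepest risers in the knockdown samples, and genes of the amino acid response driven by the transcription factor ATF4 were among those that fell furthest. CA9, a membrane carbonic anhydrase and a classic hypoxia marker, rose 119-fold, from 9.46 ± 0.62 to 1126 ± 11.4 FPKM. ASNS, asparagine synthetase, fell 41.2-fold, from 75.5 ± 4.91 to 1.83 ± 0.06 FPKM. Across the table, 2940 of the 2944 genes with a mean of at least 1 FPKM differed in limma at a Benjamini-Hochberg adjusted p under 0.05, of which 1636 were higher and 1304 were lower in the knockdown. The 4 that did not pass, named after their values were seen, were the features RPS29P16, CTB-33G10.1 and RP11-596C23.6 and the ribosomal RNA gene RNA5S7. On the log2(FPKM + 1) scale, which understates the change of genes at low level, 807 genes rose and 975 fell at least 2-fold. The range missing from the table was uneven, with rises listed from 0.70 and falls only from −1.30 among genes above 2 FPKM. A cut at 2-fold therefore leaves out listed rises more readily than listed falls. These numbers do not weigh strong rises against strong falls.

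On the log2(FPKM + 1) scale, the 8 genes with the largest rise were CA9, NDUFA4L2, NDRG1, ALDOC, SPAG4, PFKFB4, ENO2 and MT1X; the folds given here are ratios of mean FPKM, which rank genes differently. NDUFA4L2, a mitochondrial protein induced by hypoxia, rose 65.8-fold, from 3.93 ± 0.04 to 259 ± 2.29 FPKM. NDRG1, a hypoxia and stress response gene, rose 63.2-fold, from 2.50 ± 0.14 to 158 ± 2.46 FPKM. The glycolytic enzyme genes ALDOC and ENO2 rose 39.2-fold, to 183 ± 2.28 FPKM, and 26.9-fold, to 73.2 ± 0.66 FPKM. PFKFB4, a regulatory enzyme of glycolysis, rose 41.3-fold, from 0.93 ± 0.11 to 38.4 ± 0.38 FPKM, and SPAG4, a nuclear envelope protein, rose 38.9-fold, from 1.46 ± 0.06 to 56.9 ± 1.97 FPKM. MT1X, a metal-binding metallothionein, rose 19.5-fold, from 14.2 ± 0.88 to 276 ± 10.1 FPKM.

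On the same scale, the 8 genes with the largest fall were FGF21, CHAC1, ASNS, PSAT1, NUPR1, INHBE, HES1 and ADM2. FGF21, a secreted metabolic hormone, stood at 54.8 ± 2.21 FPKM in the control and at 0.00, 0.06 and 0.04 FPKM in knockdown samples 1 to 3, too close to the rounding of the table for a fold change. CHAC1, a glutathione-degrading enzyme, fell 69.7-fold, from 79.7 ± 0.83 to 1.14 ± 0.13 FPKM. PSAT1, an enzyme of serine synthesis, fell 20.8-fold to 9.40 ± 0.70 FPKM, and NUPR1, a stress-induced chromatin protein, fell 18.9-fold to 10.6 ± 0.39 FPKM. ADM2, a peptide of the calcitonin family, fell 23.5-fold, and HES1, a transcriptional repressor downstream of Notch, fell 13.4-fold, from 83.8 ± 0.62 to 6.25 ± 0.42 FPKM. INHBE, a subunit of activin, went from 15.8 ± 0.44 to 0.10 ± 0.07 FPKM, where its lowest knockdown values were also near the rounding. Adjusted p-values of these 16 genes in limma were all at most 5.676e-10.

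**Figure D1:**
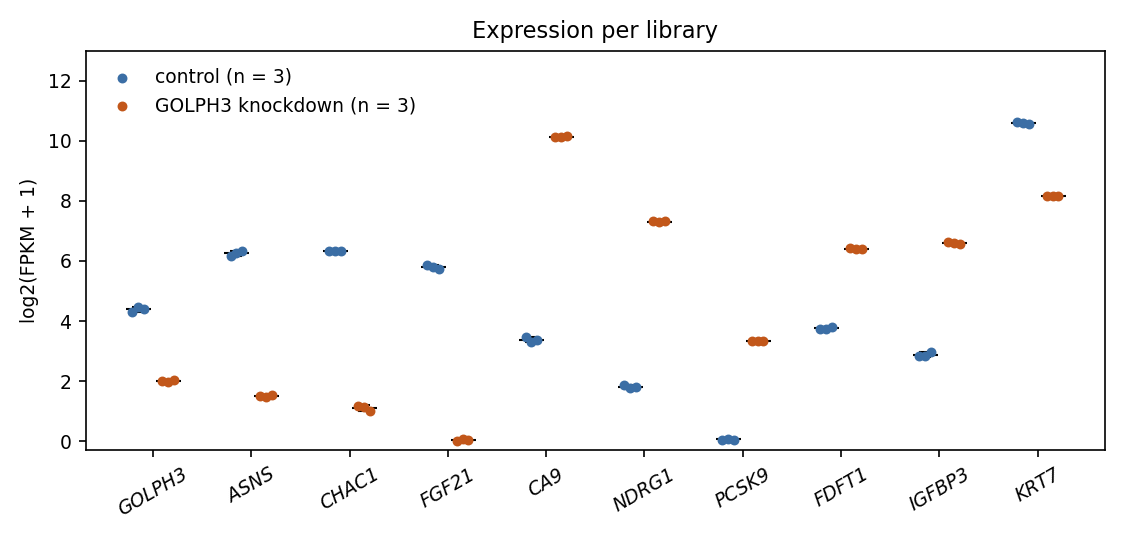
Expression of 10 genes in each library as log2(FPKM + 1), with points for the 3 control and 3 knockdown libraries and bars for the mean ± SD. GOLPH3, ASNS, CHAC1, FGF21 and KRT7 were lower and CA9, NDRG1, PCSK9, FDFT1 and IGFBP3 higher in all 3 knockdown libraries than in any control library.

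Direction went with base composition. Of the 2541 tested protein-coding genes with a transcript sequence, 6.67% were higher in the knockdown in the decile of lowest GC content (median 38.0%) and 92.9% in the decile of highest GC content (median 66.0%). Genes that rose had a median GC content of 58.7%, and genes that fell 43.6%. The rank correlation of log2 fold change with GC content across genes, which are not independent replicates, was 0.55. For this reason each gene list below with at least 5 tested members is set beside the number of risers in 10000 lists drawn from table genes of like GC content, and the median log2 fold change was compared in the same way; both comparisons were chosen after seeing the data. The count has an end. For 4 lists it could not reach an unadjusted p under 0.05 even with every member moving alike. The direction taken was down where a list had fewer risers than the drawn lists on average, and up otherwise.

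**Figure D2:**
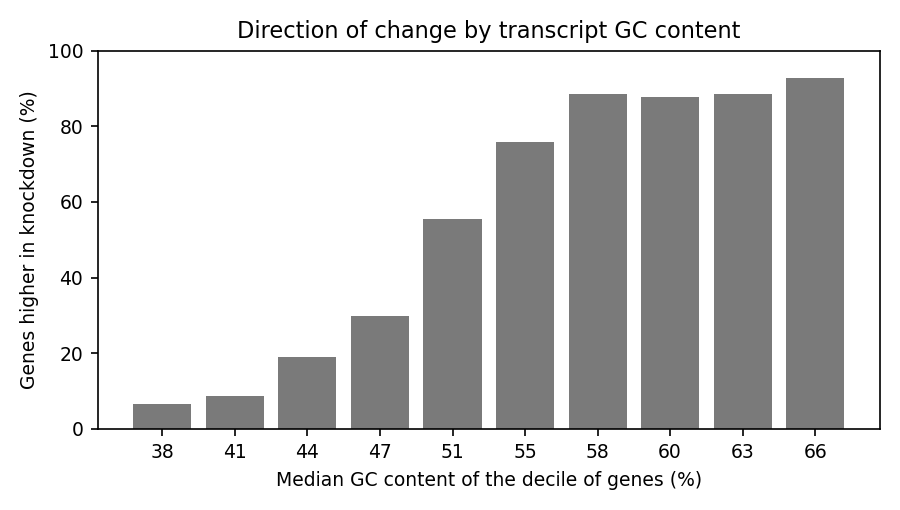
Percentage of tested protein-coding genes that were higher in the knockdown, in deciles of transcript GC content, with the median GC content of each decile below its bar. The share went from 6.67% in the lowest decile to 92.9% in the highest.

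A set of 26 gene lists had been fixed before the data were examined, and 299 of their 936 genes were in the table. Every tested member of these lists passed the limma threshold over all genes, and every one also passed adjusted over the list alone. Of the 19 lists with at least 5 tested members, 7 differed from the other genes of the table in limma's camera test with a preset correlation of 0.01, and 0 did with an estimated correlation, where the smallest adjusted p was 0.13 and 4 lists had an unadjusted p under 0.05. On ranks, camera passed for 8. For each of those 7 lists the estimated-correlation p was the highest over 21 camera alternatives. The test fry, which asks whether the members of a list move one way on balance and does not compare them with other genes, passed for 17 lists. Against lists of like GC content, 3 lists stood apart by the count of risers and 5 by the median.

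Among the decidualization markers, all 7 tested members rose, among them secreted binding proteins and signalling factors. IGFBP3, which binds insulin-like growth factors, rose 15.2-fold, from 6.33 ± 0.42 to 96.4 ± 1.51 FPKM. The cytokine gene TGFB1 rose 6.82-fold, from 18.2 ± 0.85 to 124 ± 2.92 FPKM, and CLU, an extracellular chaperone, rose 2.46-fold, from 101 ± 1.18 to 247 ± 1.74 FPKM. DKK1, GLRX, PTGES and IGFBP6 were the other members that rose. The list of 35 genes had 11 in the table, and all 11 were higher in the knockdown, the 4 below 1 FPKM untested. The camera adjusted p was 0.018, and adjusted p = 0.18 with an estimated correlation (0.00077 to 0.18 over the camera alternatives); with a mean of at least 5 FPKM it was 0.0999. In lists of like GC content 4.1 of 7 rose (adjusted p = 0.0737), and the median log2 fold change was 1.78 beside 0.69 there (adjusted p = 0.0038). With all 7 members higher, the count against those lists was already at its smallest possible unadjusted p, 0.0194. The classic markers PRL and IGFBP1 were not analysed here.

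Decidual transcription factors went both ways, with 5 of the 8 tested members higher and 3 lower. XBP1, a transcription factor of the secretory pathway, fell 3.87-fold, from 55.0 ± 2.84 to 14.2 ± 0.24 FPKM. HOXA11, a homeobox factor of the uterus, fell 3.55-fold, from 8.37 ± 0.03 to 2.36 ± 0.25 FPKM, and TEAD1, a partner of YAP, was the third that fell. FOSL2, an AP-1 subunit, rose 2.18-fold, from 7.60 ± 0.20 to 16.5 ± 0.32 FPKM, and GATA2, a zinc finger factor, rose 2.06-fold, from 7.64 ± 0.22 to 15.8 ± 0.49 FPKM. MSX2, TWIST1 and HEY1 rose as well. The list did not differ from the other genes (camera adjusted p = 0.89), its median log2 fold change and camera pointed up (0.64) while its mean was −0.02, and 4.3 risers stood in lists of like GC content (adjusted p = 1.0; 0.79 by the median). Of its 52 genes, 10 were in the table.

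The list of ATF4, the transcription factor of the amino acid and integrated stress responses, and its targets fell without exception, with 24 of 24 tested members lower. The list held 30 genes, 24 of them in the table. ATF4 itself, 1 of the 24, fell 2.85-fold, to 140.3 ± 0.91 FPKM. SLC7A5, the large neutral amino acid transporter, fell 2.81-fold, from 940.0 ± 4.30 to 334 ± 1.22 FPKM, and NUPR1 fell as given above. TRIB3, a pseudokinase of the stress response, fell 7.20-fold, from 209.7 ± 3.41 to 29.1 ± 0.99 FPKM. The camera adjusted p was 4e-08, and adjusted p = 0.16 with an estimated correlation (4.7e-12 to 0.16 over the camera alternatives). The median log2 fold change was −2.04, and in lists of like GC content 13.7 of 24 rose (adjusted p = 0.00127).

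Hypoxia and glycolysis genes rose in 27 of 29 tested members. Besides CA9 and ALDOC, PGK1, phosphoglycerate kinase, rose 6.67-fold, from 94.4 ± 3.50 to 629.6 ± 4.67 FPKM, and the glucose transporter gene SLC2A1 rose 2.55-fold, from 41.2 ± 0.92 to 105 ± 1.44 FPKM. The glycolytic enzyme gene GAPDH, often used as a reference, rose 2.70-fold, from 3971 ± 16.2 to 10707 ± 87.7 FPKM. The 2 that fell were HIF1A, which encodes the oxygen-regulated subunit of the hypoxia factor and went from 1.45 ± 0.18 to 0.56 ± 0.04 FPKM, and the vasodilator peptide gene ADM, which went from 70.7 ± 0.46 to 26.7 ± 0.65 FPKM. ENO1 rose by 0.87 on the log2 scale, a difference that was 0.0 under quantile normalization. The camera adjusted p was 7.7e-05, and adjusted p = 0.13 with an estimated correlation (6.3e-08 to 0.13 over the camera alternatives); in lists of like GC content 17.5 of 29 rose (adjusted p = 0.00127).

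Cholesterol synthesis and uptake genes rose in 17 of 17 tested members, with a median log2 fold change of 1.56. FDFT1, squalene synthase, rose 6.65-fold, from 12.7 ± 0.38 to 84.1 ± 0.38 FPKM. PCSK9, which lowers LDL receptors, went from 0.043 ± 0.006 FPKM, near the rounding of the table, to 9.11 ± 0.006 FPKM. INSIG1, a sterol-regulated protein of the endoplasmic reticulum, rose 17.8-fold, from 1.17 ± 0.09 to 20.8 ± 0.61 FPKM, and LDLR, the LDL receptor, rose 4.85-fold, from 4.67 ± 0.10 to 22.7 ± 0.46 FPKM. The camera adjusted p was 0.00046, and adjusted p = 0.13 with an estimated correlation (1.4e-05 to 0.13 over the camera alternatives). In lists of like GC content 10.2 of 17 rose (adjusted p = 0.00127).

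Splicing factor genes fell in 15 of 15 tested members, and all 24 in the table were lower in the knockdown. The list held 64 genes, and those outside the table, which lacks small differences, were not analysed. LUC7L, a factor bound to the U1 particle, fell 4.22-fold, from 9.38 ± 0.28 to 2.22 ± 0.12 FPKM, and TIAL1, an RNA-binding regulator, fell 2.89-fold, from 7.95 ± 0.13 to 2.75 ± 0.03 FPKM. SRSF3, a serine- and arginine-rich factor, fell 2.62-fold, from 20.8 ± 1.12 to 7.95 ± 0.11 FPKM, and RBM39 fell 3.49-fold, from 8.19 ± 0.36 to 2.35 ± 0.04 FPKM. The camera adjusted p was 0.00026, and adjusted p = 0.2 with an estimated correlation (1.6e-06 to 0.2 over the camera alternatives). These genes had a low median GC content, 41.1%, and in lists of like GC content only 2.7 of 15 rose, so that the count of risers could not have passed (adjusted p = 0.162). The median log2 fold change was −1.28 beside −1.08 in those lists (adjusted p = 0.271).

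Neither of the Golgi lists differed from the other table genes in camera. Of the 10 tested Golgi glycosylation enzymes 9 rose and ST3GAL1 fell. GALNT2, which starts O-glycosylation, rose 3.29-fold, from 7.75 ± 0.19 to 25.5 ± 0.18 FPKM, and MGAT4B, an N-glycan branching enzyme, rose 2.13-fold, from 16.2 ± 0.36 to 34.5 ± 0.27 FPKM. The camera adjusted p was 0.073, and 7.5 of 10 rose in lists of like GC content (adjusted p = 0.66; 0.968 by the median). Among genes of Golgi structure and vesicle coats 4 rose and 5 fell (camera adjusted p = 0.77). KDELR1, a retrieval receptor, rose 2.33-fold, from 70.9 ± 1.02 to 165 ± 0.86 FPKM, and the cargo receptor gene TMED9 rose 2.30-fold, from 39.0 ± 0.70 to 89.5 ± 1.51 FPKM. Of the GOLPH3 partners and PI4P genes, 4 were tested, too few for a list test. The GOLPH3-binding myosin gene MYO18A rose 2.64-fold, from 1.42 ± 0.05 to 3.76 ± 0.08 FPKM, while PITPNB, a phosphatidylinositol transfer protein, fell 2.68-fold, from 5.22 ± 0.34 to 1.95 ± 0.03 FPKM, and VPS26A and PI4K2B also fell.

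Matrix and growth factor genes were mostly higher. Of 21 tested extracellular matrix genes 17 rose, among them COL5A1, a fibrillar collagen chain, which rose 2.96-fold, from 25.7 ± 0.14 to 75.9 ± 0.71 FPKM. The 4 that fell were CCN2, THBS1, COL12A1 and CCN1, a matricellular protein, which fell 5.75-fold, from 247 ± 9.05 to 43.0 ± 0.99 FPKM. The list did not pass camera (adjusted p = 0.061). All 12 tested WNT, BMP and TGF-beta signalling genes rose, and ID1, an inhibitor of helix-loop-helix factors, rose 2.99-fold, from 153 ± 4.18 to 459 ± 10.9 FPKM. Of the 54 genes of the signalling list 26 were in the table, and TGFB1 and DKK1 also count among the decidualization markers. That list passed camera (adjusted p = 0.01; adjusted p = 0.16 with an estimated correlation, 0.0079 to 0.16 over the camera alternatives). It did not pass with no filter (0.1136) or with a mean of at least 5 FPKM (0.1005), and of its 14 members below the filter 8 were lower in the knockdown. Like-GC lists held 13.8 of 21 risers for the matrix list (adjusted p = 0.239) and 8.7 of 12 for the signalling list (adjusted p = 0.0737). By the median the adjusted p-values were 0.223 and 0.323. With all 12 signalling genes higher, their count against those lists was already at its smallest possible unadjusted p, 0.0162.

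Markers of cell types also differed. All 7 tested stromal fibroblast markers rose (camera adjusted p = 0.029; adjusted p = 0.18 with an estimated correlation, 0.0059 to 0.18 over the camera alternatives; 0.1005 with a mean of at least 5 FPKM). S100A4, a calcium-binding protein, rose 7.53-fold, from 82.6 ± 0.91 to 622 ± 3.30 FPKM, and P4HB, a subunit of prolyl hydroxylase, rose 2.03-fold, from 64.8 ± 0.19 to 132 ± 0.85 FPKM. Like-GC lists held 5.1 of 7 risers, too many for the count to pass (adjusted p = 0.236), and had the same median log2 fold change, 0.84 (adjusted p = 0.997). The matrix genes DCN and COL3A1 of this list, abundant in most stromal fibroblasts, lay near 0, at 0.03 ± 0.02 and 0.007 ± 0.006 FPKM in the control and 0.137 ± 0.006 and 0.13 ± 0.046 FPKM in the knockdown. DCN is also among the 11 decidualization markers in the table. Of 5 tested epithelial markers 4 rose and 1 fell (camera adjusted p = 0.32), with a median log2 fold change of 2.10 beside 0.92 in like-GC lists (adjusted p = 0.0175). The keratin gene KRT7 was abundant in the control and fell 5.41-fold, from 1552 ± 34.9 to 287 ± 2.54 FPKM, while KRT18 rose 2.08-fold, from 379 ± 3.95 to 786 ± 11.7 FPKM, and the mucin gene MUC1 rose 10.3-fold, from 4.09 ± 0.05 to 42.2 ± 0.49 FPKM. The pericyte marker CSPG4 rose 3.67-fold to 16.3 ± 0.37 FPKM and the endothelial marker EGFL7 rose 2.44-fold to 40.4 ± 1.08 FPKM. The 5 leukocyte markers in the table, CD68, CD74, CSF1R, HLA-DRA and LAPTM5, lay below a mean of 1 FPKM and were not tested. All 5 had higher means in the knockdown, as for CD74 with 0.163 ± 0.021 against 1.13 ± 0.098 FPKM.

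**Figure D3:**
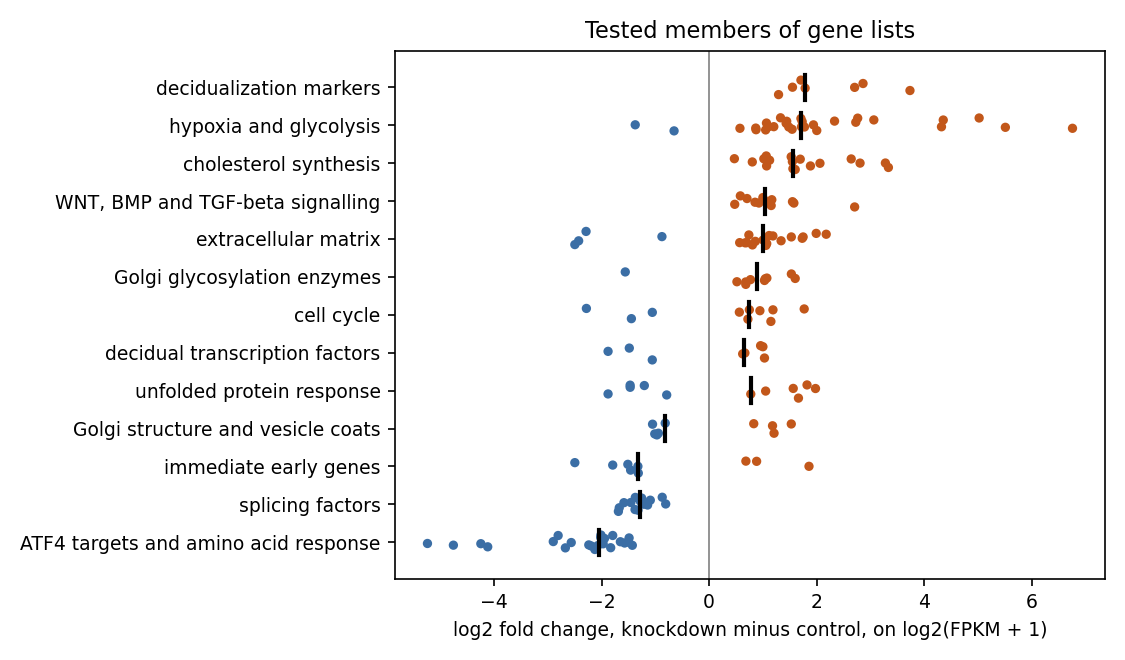
Change of the tested members of 13 gene lists, as log2 fold change of knockdown minus control on the log2(FPKM + 1) scale, with a point per gene and a black line at the list's median. All 24 members of the ATF4 list, ATF4 among them, and 15 splicing factors lie below 0 and all 17 cholesterol genes above it. Of the hypoxia genes, 27 of 29 lie above 0, ENO1 among them, which was at 0.0 under quantile normalization.

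Other lists went both ways and did not pass camera. Against lists of like GC content, the lists of this paragraph and the interferon, epithelial and Golgi structure lists had adjusted p-values of 0.162 to 1.0 for the count of risers, and all but the epithelial list 0.0722 to 0.997 for the median. The PI3K, AKT and mTOR list (2 rose, 3 fell; adjusted p = 0.6) held EIF4EBP1, a repressor of cap-dependent translation, which fell 5.05-fold, from 899 ± 36.4 to 178 ± 1.60 FPKM, and SESN2, a stress-induced inhibitor of mTOR, which fell 4.25-fold, from 64.2 ± 1.35 to 15.1 ± 0.33 FPKM. In the cell cycle list (7 rose, 3 fell; adjusted p = 0.5) CCND1, a cyclin of the first gap phase, fell 5.38-fold, from 40.3 ± 1.01 to 7.5 ± 0.21 FPKM, and the mitotic kinase gene AURKB rose 2.31-fold, to 87.8 ± 1.46 FPKM. Of the unfolded protein response genes 6 rose and 5 fell (adjusted p = 0.89), with CALR and SDF2L1, chaperones of the endoplasmic reticulum, 3.17-fold and 3.68-fold higher. In the p53 and apoptosis list (4 rose, 4 fell; adjusted p = 0.89) GDF15, a stress cytokine, fell 4.71-fold and CDKN1A, a cell cycle inhibitor, rose 2.17-fold. SESN2 and GDF15 also count among the fallers of the ATF4 list. Among contractile genes (3 rose, 4 fell; adjusted p = 0.63) DES, desmin, went from 0.40 ± 0.03 to 7.56 ± 0.16 FPKM, and TPM1, tropomyosin, fell 4.44-fold. Immediate early genes (3 rose, 6 fell; adjusted p = 0.23) included CCN1 and the phosphatase gene DUSP1, which fell 2.79-fold, from 116 ± 2.62 to 41.6 ± 1.01 FPKM.

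Interferon response genes rose in 4 of 5 tested members, and STAT1 fell (camera adjusted p = 0.36). BST2, a tether of budding virus, rose 2.20-fold, from 190 ± 3.37 to 419 ± 6.66 FPKM, and ISG20, an exonuclease, rose 8.39-fold, from 0.40 ± 0.09 to 3.38 ± 0.07 FPKM. All 3 inflammatory genes in the table fell, with IL6 9.43-fold lower, from 38.4 ± 2.27 to 4.07 ± 0.40 FPKM, and CXCL2 2.96-fold lower, from 6.80 ± 0.62 to 2.30 ± 0.47 FPKM; CXCL3 was the other. Of the 63 cytosolic ribosomal protein genes, 2 were in the table, and RPL7A rose 1.96-fold, to 2412 ± 26.3 FPKM, and RPL18 rose 1.65-fold, to 429 ± 7.57 FPKM. SDHA and COX7A2, subunits of respiratory complexes, rose 2.85-fold and 1.90-fold, and SDHC, the other tested gene of that list, rose too. The mitochondrially encoded MT-ND3 rose 1.76-fold, from 4233 ± 76.7 to 7446 ± 226 FPKM, and was lower under quantile normalization, by a log2 fold change of −0.31. Metallothioneins, ribosomal proteins, keratins, GAPDH and MT-ND3 have near-identical copies or pseudogenes elsewhere in the genome, so their levels are uncertain where reads could be shared.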

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

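The offset scaling was chosen after seeing the data; the other alternatives were planned. Over 19 alternatives, or fewer where a filter removed the gene, the 63 named genes kept direction and call with 1 exception: MT-ND3 was −0.3083 under quantile normalization, and the cause was not tested. Apart from GOLPH3, these genes were chosen for large changes or small p, from a table that lacks small differences. Their stable direction was therefore largely fixed in advance, and no conclusion is drawn from it. GOLPH3 ranged from −3.29 to −2.16. Filters changed how many genes were tested and so the counts: with no filter 5911 genes changed, 3228 up and 2683 down, and with a mean of at least 5 FPKM 1354 changed, 877 up and 477 down, 982 of them at least 2-fold. Leaving out 1 sample gave 2884 to 2943 changed genes. The replicate numbers gave no clear sign of pairing, though 3 samples per group cannot exclude it. Pairing was sought in what was left after each group's mean per gene was subtracted, over 867 genes above 5 FPKM in all samples. There the correlations of same-numbered control and knockdown samples were −0.043, 0.171 and −0.214. The highest between any control and any knockdown sample was 0.275. With the replicate block 2941 genes changed and 7 lists passed. Of the gene lists, 4 passed with a mean of at least 5 FPKM, 0 with an estimated correlation and 17 with fry, which asks another question. The median of the unfolded protein response list was −0.333 with no filter, over 15 genes instead of 11. The median of the p53 list, −0.03 over 4 genes up and 4 down, was 0.17 with the offset scaling, which raises all knockdown values. It was −0.052 to 0.764 when 1 sample was left out: 0.757, 0.764 and 0.753 without control replicates 1, 2 and 3, where 7 of the 8 genes passed the filter, so that the median was that of a riser. The matrix list passed camera with no filter (adjusted p = 0.009444) and on ranks (0.04417), in a range of 0.0094 to 0.43 over the camera alternatives. Of the 10 splits of the 6 samples into 3 and 3, the real one gave 2940 genes and the highest other gave 1. With 10 splits no share under 0.05 is possible. The table lacks genes with small differences between the groups, so a mixed split puts large differences into the spread and can call few genes. That contrast was largely fixed in advance, and no conclusion is drawn from it. Rounding to 2 decimals limits low values such as that of FGF21 in the knockdown.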

Other observations

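The lists of this part were written after some values had been seen, and the tests by GC-matched lists, of a scaling factor, of replicate spread and of the gap in fold changes were chosen after the results they concern; the tests of GC bias among libraries and lncRNA genes, of transcript length and of ribosome biogenesis were set before theirs.

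Genes of ribosome assembly fell together. Of 65 tested members of a ribosome biogenesis list 63 fell and 2, FBL and IMP3, rose. The list held 124 genes, 75 of them in the table. Members whose values had been seen before were left out. NOL7 fell from 76.0 ± 4.32 to 12.8 ± 0.16 FPKM, DKC1, the pseudouridine synthase of small nucleolar particles, from 58.2 ± 3.07 to 10.1 ± 0.34 FPKM, and NCL, nucleolin, from 82.6 ± 5.13 to 21.1 ± 0.58 FPKM (SD, n = 3). A hypothesis that the list fell beyond the GC trend was tested against lists of like GC content (median 44.9%). In those lists 22.3 members rose, with an adjusted p of 0.0006. The draws took members as independent, so p is too small where members move together. All 12 small nuclear and all 8 small nucleolar RNA genes in the table had lower means in the knockdown, counted at any level and without a test. Reads of such multicopy genes are hard to place, and the libraries were made with an mRNA kit. These values are therefore not a reliable measure of those RNAs. Cytosolic aminoacyl-tRNA synthetase genes, which load amino acids onto tRNA and of which 4 are also in the ATF4 list, fell in 14 of 15 tested members, and QARS1 rose. Without those 4, whose fall was known, 10 of 11 fell, against 3.9 risers in like-GC lists (unadjusted p = 0.0478).

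All 5 tested metallothioneins, small metal-binding proteins, rose, MT2A from 326 ± 15.6 to 1904 ± 37.1 FPKM and MT1E from 217 ± 7.34 to 929 ± 11 FPKM; the list was drawn up after the rise of MT1X, 1 of the 5, had been seen, so no test of it is given. HMOX1, haem oxygenase, chosen after its values were seen, rose 19.1-fold, from 11.3 ± 0.27 to 215 ± 0.86 FPKM. GOLPH3-DT, the divergent lncRNA gene that starts beside GOLPH3 on the plus strand (chromosome 5, 32174471 to 32175272), also chosen after its values were seen, rose 2.03-fold, from 18.5 ± 0.71 to 37.4 ± 0.77 FPKM, while GOLPH3 fell. The matrix genes DCN, COL3A1 and COL6A3 stood at 0.03, 0.007 and 0.017 FPKM in the control and at 0.137, 0.13 and 0.04 FPKM in the knockdown. KRT7, an epithelial keratin, stood at 1552 and 287 FPKM. These levels are unusual for stromal fibroblasts, but the markers were mixed. In the control the stromal markers S100A4 and P4HB stood at 82.6 and 64.8 FPKM, and the keratin gene KRT19 at 0.133 FPKM. Of 9 stromal markers present, 7 had a mean of at least 1 FPKM, as had 5 of 7 epithelial markers. Markers outside the table were not analysed, so these levels do not decide whether the stromal label holds. The reading of the stromal and decidualization lists rests on that label, and the identity of the cells was not tested.

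The direction of change followed transcript GC content, with a slope of 0.878 log2 units per 10 points of GC between the groups. A GC bias that varies from library to library is argued against among the genes of this table. The largest slope between replicates was 0.049, 5.6% of the slope between the groups. The table lacks small differences between the groups, which can raise that slope but not those between replicates. Over all genes the share could be higher. Transcript length is argued against as well, since the rank correlation with GC content within quintiles of length was at least 0.51. A GC bias shared by all libraries of a group cannot be told apart from an effect of the knockdown: among lncRNA genes the rank correlation was 0.16, between the bounds set for the 2 answers. The splicing factors, which fell, had a median log2 fold change of −1.28, beside −1.08 in lists of like GC content (adjusted p = 0.271), so a fall beyond the GC trend was not shown and the same open question covers them.

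ATF4 targets fell while hypoxia and cholesterol genes rose. The GC trend as the whole cause is argued against. Each of the 3 lists had an adjusted p of at most 0.00127 against lists of like GC content. Those draws took members as independent, so p is too small where members move together. The correlation among members was estimated at 0.13 in the ATF4, −0.03 in the hypoxia and −0.04 in the cholesterol list. These estimates rest on 3 samples per group that may be technical replicates, so they cannot show how far members move together. With estimated correlations, camera gave adjusted p of 0.16, 0.13 and 0.13 for these lists. As the whole cause, 1 scaling factor per library is argued against too, since it would move all genes alike. The ATF4 median lay 3.6 log2 units below the lower of the other medians, and its upper quartile (−1.82) below their lower quartiles (1.10 and 1.07). With lists picked for a fall or a rise in a table without small changes, such a gap was bound to appear. It shows only that 1 factor cannot give both directions. A candidate explanation that remains is a difference in culture conditions between the groups, such as oxygen, medium or cell density, because members varied within a group by a median of 2.8% and replicates grown together would look like this. An effect of GOLPH3 loss would give the same values, so the design cannot separate these.

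No gene of the table lay between a log2 ratio of −1.30 and 0.70 among genes above 2 FPKM. This gap may come from selection at 2-fold on a scale shifted against FPKM by 0.302, since its half-width was 0.998 log2 units. No biological explanation was tested for it. The rule of the selection is not given in the sources used here.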
